A study of Mus musculus with 8 samples.

How the data were processed

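Gene expression was measured by bulk RNA sequencing in primary neurospheres, which are floating clusters of cultured neural stem cells, from embryonic mouse brain. By the labels, 4 libraries were wild type and 4 were from Phf23 knockout cells. Per the labels' protocols, cells were lysed in TRIzol, polyadenylated RNA was taken and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes, FastQC 0.12.1, fastp 0.23.4, STAR 2.7.1a and DESeq2 1.38.3 were used, with the mm10 genome build. The read counter, the annotation, any use of strand and any filter on genes are not given in the sources used here.

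The deposited signal values were gene read counts divided by 1 size factor per library. This was checked on the values: all values of a library were whole multiples of 1 step, so that whole reads were recovered for 100% of values in each library at a tolerance of 1e-04 reads. Recovered depth ran from 15647304 reads in wild type 3 to 19462516 in Phf23 knockout 3, and size factors from 0.889 to 1.07. The table had 15602 rows, of which 64 repeated another row and were dropped, leaving 15538 genes. The lowest gene mean was 1.30 normalised reads, so a minimum mean of 1 and the absence of a filter removed nothing. The lowest gene total was 11 recovered reads over the 8 libraries, so genes with fewer reads had been left out before deposit. There were 0 columns of samples outside the series.

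Identifiers were matched to GENCODE mouse release M21, which annotates the assembly that mm10 denotes. A symbol was found for 15535 genes and an annotated transcript for 15531, and 14733 genes were protein-coding. Coordinates are 1-based. Where genes overlap, reads cannot be told apart, because the counting is not described.

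The test planned for raw counts was the quasi-likelihood test of edgeR. Because the deposited values were normalised, the test planned for that case was used: limma-trend with robust empirical Bayes (limma 3.58.1 in R 4.3.3) on log2(value + 1), with genotype as the only term. It was two-sided with Benjamini-Hochberg adjustment over all 15538 genes, and a gene was called at a false discovery rate (FDR) under 0.05. Every FDR given for a gene without another tool's name is from this test. Log2 fold changes are on the log2(value + 1) scale, which understates changes of genes with few reads, and run from libraries labelled wild type to libraries labelled knockout. Gene values are means of normalised reads ± SD over the 4 libraries of a genotype, and a log2 fold change is given ± SE. Measures of whole libraries were compared by a two-sided exact permutation test, whose smallest possible p is 0.0286.

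Before the data were examined, the groups, the tests, the gene lists and the rule for named genes were fixed. Of 33 lists, 30 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 30 lists. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance one way, were alternatives. The rule named Phf23 and Tcf4, up to 4 members of each list with the lowest FDR, and the 12 largest positive and 12 largest negative log2 fold changes. Genes of this last kind had to be called, with a mean of at least 1 normalised read, no overlap between genotypes and no predicted or clone-derived name. Genes and families outside the rule are named in the closing observations and for the sex-linked genes, and were chosen after their values were seen. Some genes that the rule or the observations would name are not reported here, in the text or in the plot of lineage genes.

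The other settings fixed in advance were edgeR 4.0.16 with DESeq2 size factors, with library size only, without a filter, and with at least 10 reads in at least 4 libraries. DESeq2 1.42.0, limma-voom, a replicate block, a pseudocount of 0.1, a minimum mean of 1, a log2 fold change of at least 1 and leaving out each library in turn were also fixed. After the data were seen, 10 alternatives were added. They were edgeR with TMM scaling on the recovered reads, limma-trend with TMM, limma-trend with library size only, a minimum mean of 10, 3 that concern transcript length, and camera with an estimated correlation in each of those 3. In the first of the 3, a loess trend (span 0.3) with transcript length and GC content was subtracted from each library. Length and GC content were those of the longest annotated transcript of each gene, which need not be the one expressed. In another, the length slope of each library entered the model as a covariate. That slope was estimated over 13265 genes with a mean of at least 10 normalised reads. In the last, the 4 libraries with the steepest slopes (wild type 1 and 2 and Phf23 knockout 1 and 2) were left out. This left wild type 3 and 4 against Phf23 knockout 3 and 4. With so few libraries, an FDR of that fit rests mostly on variance shared across genes. The edgeR test on the recovered reads called 4683 of 13324 genes.

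The tests were checked on simulated data for 4 against 4 libraries and 15538 genes, of which 200 were changed (random seed 11; shuffles used seed 7). Limma-trend recovered 54% of 1.5-fold and 96% of 2-fold changes with 7 false calls. The changed genes were drawn only from well expressed genes, so recovery for genes with few reads was not checked. With the length trend of these libraries added, it made 523 false calls. Subtracting the trend left 13 false calls and recovered 49% of 1.5-fold and 95% of 2-fold changes. With the slope as a covariate, 2% and 28% were recovered, with 5 false calls. The spread of the simulated genes was estimated with genotype as the only term. It thus already held spread that goes with the slope. The recovery of the covariate fit and the 523 false calls may therefore both be understated. The added trend was a straight slope with length, without GC content. Camera called 1 of 1 raised lists and 0 of 20 unchanged lists. That check used genes drawn independently and without a length trend, so it could not test the preset correlation. In the libraries themselves, 24 of the 35 splits into 4 and 4 called at least 1 list, the real split included. Replicates were compared in pairs before averaging, and their chi-square per degree of freedom lay between 5.99 and 78.4, so no pair agreed within sampling noise and no library was left out. Tables and figures were made with Python 3.11.15.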

Results

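The data were gene-level read counts from 8 bulk RNA-seq libraries of primary embryonic mouse neural stem cells grown as neurospheres. The labels put 4 libraries in a wild-type group and 4 in a group homozygous for loss of Phf23, a PHD-finger chromatin protein. Recovered depth ran from 15647304 to 18241215 reads in the libraries labelled wild type and from 18099114 to 19462516 in those labelled knockout (n = 4 each, two-sided exact permutation p = 0.114). By the series' own description, loss of Phf23 blocks the differentiation of these cells, and histone acetylation at Tcf4 is named as the step involved. Gene counts in these libraries measure neither directly. Nothing in the labels says that the replicates came from separate cultures or animals, so p-values measure only the spread between these libraries, which may be technical.

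Phf23 itself was higher in the libraries labelled knockout. Phf23 (ENSMUSG00000018572, chromosome 11, 69995777 to 70000009, plus strand, mm10) had 720, 766, 788 and 919 normalised reads in the libraries labelled wild type 1 to 4. It had 1607, 1528, 1429 and 1361 in those labelled Phf23 knockout 1 to 4. The means were 798 ± 85.4 and 1481 ± 108 (SD, n = 4 each), a 1.86-fold difference. The log2 fold change was 0.89 ± 0.106 (95% interval 0.66 to 1.12, limma-trend FDR = 0.000581). It was 0.54 ± 0.0694 (limma-trend FDR = 0.000185) once a trend with transcript length and GC content was subtracted from each library. The targeted gene thus went against its label, and every direction below is between libraries as labelled. A gene total sums reads over all exons, so it does not check a deletion of part of the gene.

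**Figure D1:**
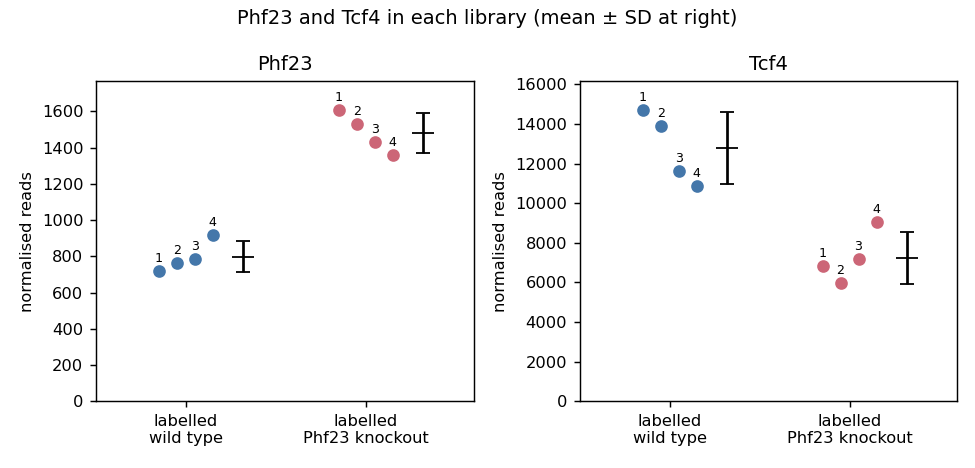
Normalised reads of Phf23 (left) and Tcf4 (right) in each library by labelled genotype, with points numbered by replicate and the mean ± SD of 4 libraries beside them. The libraries labelled knockout lie between 1361 and 1607 for Phf23, above the highest wild-type value of 919, and below the wild-type libraries for Tcf4.

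Tcf4, which encodes a basic helix-loop-helix E protein, was lower in the libraries labelled knockout. Tcf4 (ENSMUSG00000053477, chromosome 18, 69343356 to 69689079, plus strand, mm10) had 14691, 13889, 11634 and 10860 normalised reads in wild type 1 to 4 and 6807, 5965, 7183 and 9068 in the libraries labelled Phf23 knockout 1 to 4. The means were 12769 ± 1815 and 7256 ± 1311 (SD, n = 4 each), a 1.77-fold difference. The log2 fold change was -0.82 ± 0.140 (95% interval -1.12 to -0.52, limma-trend FDR = 0.00369). The longest annotated Tcf4 transcript has 8577 nt, and among 200 genes of like length, GC content and expression the median log2 fold change was -0.41, with 4.5% of them below Tcf4. With the length and GC trend subtracted, Tcf4 was at -0.29 ± 0.0638 (FDR = 0.00729). The call ended with the length slope of each library as a covariate (log2 -0.31 ± 0.108, FDR = 0.27). Without the 4 libraries of the steepest length slopes Tcf4 was called at -0.48 (FDR = 0.000405). That fit compares only wild type 3 and 4 with Phf23 knockout 3 and 4, so its FDR rests mostly on variance shared across genes.

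Short transcripts were higher and long transcripts lower in the libraries labelled knockout. The length slope, in log2 units per doubling of transcript length, was 0.26, 0.20, 0.08 and 0.06 in wild type 1 to 4. It was -0.24, -0.31, -0.09 and 0.04 in the libraries labelled Phf23 knockout 1 to 4 (two-sided exact permutation p = 0.0286, the smallest possible). Across 13265 genes, which are not independent replicates, the Spearman correlation of the log2 fold change was -0.598 with transcript length and 0.393 with GC content. Of the tenth of genes with the shortest transcripts (297 to 1473 nt), 669 rose and 18 fell. Of the tenth with the longest (6992 to 123179 nt), 19 rose and 762 fell. Cytosolic ribosomal protein genes have short transcripts. Genes with a symbol of Rpl or Rps plus a digit, a rough stand-in for them, took 3.31 ± 0.432% of normalised reads in wild type and 4.58 ± 0.922% in the libraries labelled knockout (SD, n = 4 each, exact permutation p = 0.0857). That symbol rule misses Rpsa and the Rplp genes and admits Rps6k kinase genes. Mitochondrially encoded genes took 3.42 ± 0.636% and 3.49 ± 0.852% (SD, n = 4 each, exact permutation p = 0.886).

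**Figure D2:**
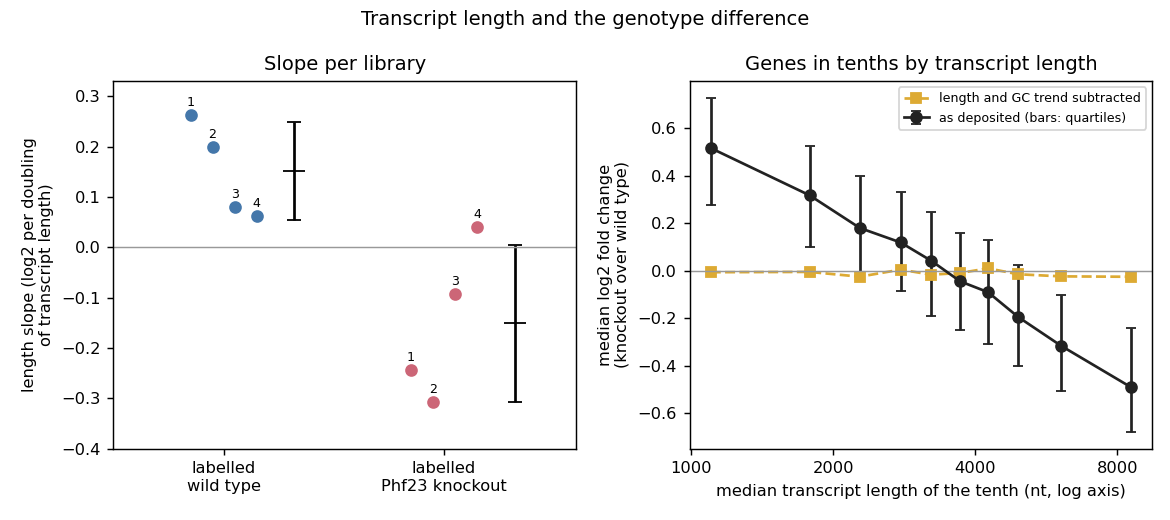
Left, the length slope of each library (log2 units per doubling of transcript length) by labelled genotype, with points numbered by replicate and the mean ± SD of 4 libraries beside them. Right, the median log2 fold change of genes in 10 groups by transcript length (nt, log axis, bars are quartiles), which goes from 0.517 to -0.492 as deposited and lies near 0 with the length and GC trend subtracted.

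In all, 4593 of 15538 genes were called by limma-trend, 2301 higher and 2292 lower in the libraries labelled knockout. Scaling by library size only gave 1827 higher and 2757 lower, with a median shift of -0.06 over all genes. The change was at least 2-fold for 247 genes that rose and 309 that fell. Genotypes did not overlap for 27.7% of genes, against 2.86% by chance. The count of calls was 2189 without wild type 1, 2106 without wild type 2 and 1884 without Phf23 knockout 1. It was 2826 with the length and GC trend subtracted, of which 1854 were shared with the 4593 in the same direction, and 1422 without the 4 libraries of the steepest slopes, of which 1188 were shared. It was 170 with the length slope as a covariate, of which 127 were shared. On simulated data with 15538 genes that fit recovered 28% of 2-fold changes, a share that may be understated. Of 115 called genes named under the fixed rule, 84 kept the call when any 1 library was left out, 82 with the trend subtracted, 75 without the 4 libraries and 16 with the covariate. These genes were picked from the same data, mostly by low FDR or large change. Of all 4593 calls, 40.4% were kept with the trend subtracted, 25.9% without the 4 libraries and 2.77% with the covariate. The log2 change shrank by over 1.5 times or reversed for 55, 46 and 55 of the 115 in these 3 fits. Among the 16 were Phf23, Akr1b7, Nr2f2, Hes5, Tnc, Aldh1l1, Bcas1, Sox10, Cdh19, Sesn2, Lgr5, Shh, Egln3, Zic1 and Ebf1.

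Nr2f2, which encodes the nuclear receptor COUP-TFII, fell from 228 ± 25.5 to 30.2 ± 6.51 normalised reads (7.42-fold lower, log2 -2.89 ± 0.186, FDR = 1.6e-05). Akr1b7, an aldo-keto reductase gene, rose from 46.9 ± 14.2 to 215 ± 16.8 (log2 2.22 ± 0.214, FDR = 0.000297), and the myelin gene Mbp rose from 46.2 ± 19.4 to 193 ± 14.9 (log2 2.16 ± 0.289, FDR = 0.00103). The zinc finger gene Zkscan16 fell from 66.1 ± 14.3 to 15.4 ± 11.9 (FDR = 0.00661) and the corepressor gene Lcor fell from 400.3 ± 122 to 106 ± 94.0 (FDR = 0.00853). Zkscan16 and Lcor were at -0.48 and -0.23 on the log2 scale with the length slope as a covariate, against -2.34 and -2.24, and at -1.16 and -1.02 without the 4 libraries of the steepest slopes. With the trend subtracted, Lcor missed the threshold with a change about as large (log2 -1.97 against -2.24, FDR = 0.0513).

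The other genes of largest change had few reads. Sdsl rose from 11.1 ± 5.89 to 48.9 ± 11.4 normalised reads, Cartpt from 6.73 ± 4.88 to 31.3 ± 13.1 and Enpp6 from 5.82 ± 1.40 to 25.8 ± 4.37. Capn11 rose from 3.80 ± 1.06 to 20.4 ± 7.11, Fxyd2 from 2.25 ± 1.99 to 11.8 ± 3.0 and the myelin glycoprotein gene Mag from 1.09 ± 1.59 to 8.67 ± 3.74. Serpinb11 rose from 0.240 ± 0.480 to 4.84 ± 2.29 and Slco2a1 from 2.08 ± 2.42 to 9.87 ± 5.85. Mup6 and Lrrc25 had 0 reads in the 4 wild-type libraries and 21 each in those labelled knockout, at least 6.82-fold higher against a floor of 3 reads over the group. This floor covers counting error only. Slc35d3 fell from 15.1 ± 5.02 to 1.67 ± 2.05, Actl10 from 10.2 ± 1.08 to 1.45 ± 2.29 and Ptchd1 from 14.6 ± 7.65 to 1.48 ± 0.593. Tktl1 fell from 8.05 ± 2.49 to 0.726 ± 0.923, the hyaluronan synthase gene Has1 from 7.39 ± 3.83 to 0.485 ± 0.560 and Fgd5 from 13.6 ± 4.04 to 1.73 ± 0.970. The haptoglobin gene Hp fell from 5.82 ± 1.81 to 0.465 ± 0.930, Pabpc5 from 34.8 ± 17.0 to 6.99 ± 4.50 and Xkr4 from 17.6 ± 10.6 to 3.45 ± 2.77. With the slope covariate, Cartpt, Fxyd2 and Pabpc5 were at 0.80, 1.13 and -0.43 on the log2 scale, against 2.19, 2.20 and -2.27. Without the 4 libraries of the steepest slopes, Sdsl (log2 2.16 with all 8), Cartpt and Pabpc5 were at 1.42, 1.13 and -1.08. There, Cartpt, Fxyd2, Mag, Serpinb11, Mup6, Lrrc25, Ptchd1, Has1, Hp and Pabpc5 were not called (FDR from 0.0761 to 0.275). Mag lost its call without Phf23 knockout 1 (log2 2.23, FDR = 0.0539), Serpinb11 without Phf23 knockout 1 (log2 1.99, FDR = 0.0611), Pabpc5 without wild type 2 (log2 -2.05, FDR = 0.0506) and Xkr4 without wild type 1 (log2 -1.90, FDR = 0.0646). Slco2a1 lost it without wild type 1 (log2 1.74, FDR = 0.0865), wild type 4 (log2 1.74, FDR = 0.0672), Phf23 knockout 1 (log2 2.19, FDR = 0.0702) or Phf23 knockout 3 (log2 1.80, FDR = 0.0885). Lrrc25 stayed called only without Phf23 knockout 2 or Phf23 knockout 4 (log2 from 1.75 to 2.17 and FDR from 0.0554 to 0.131 without each other library, against log2 2.17 with all 8), and it was not called with the trend subtracted (log2 1.70 against 2.17, FDR = 0.117).

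Neural stem cell and radial glia genes moved in both directions, with 8 higher and 2 lower of 24 measured (10 and 3 adjusted over the list alone, median log2 fold change 0.16, camera FDR = 0.129). For lists with no second count, the count adjusted over the list alone was the same. The Notch effector gene Hes5 rose from 472 ± 70.8 to 1524 ± 398 normalised reads (log2 1.67, FDR = 0.000332), and it was at 0.95 with the trend subtracted, where the call ended (FDR = 0.107). The glutamine synthetase gene Glul rose from 5002 ± 212 to 7269 ± 544, Sox3 rose from 2381 ± 811 to 4553 ± 586 and the tenascin C gene Tnc fell from 25252 ± 2007 to 13837 ± 1827 (FDR = 0.00413, 0.00684 and 0.000968). After subtraction of the trend, 7 higher and 1 lower were called, and the list was called as higher (camera FDR = 0.0337), but not with an estimated correlation (adjusted p = 0.678). The list of intermediate progenitor and proneural genes had 5 higher and 2 lower of 18 measured (5 and 3 adjusted over the list alone, median log2 fold change 0.26, camera FDR = 0.286). Btg2 rose from 1019 ± 49.2 to 1484 ± 122, Hes6 rose from 889 ± 246 to 1785 ± 439 and Tcf12, which encodes another E protein, fell from 7834 ± 782 to 5209 ± 859 (FDR = 0.00485, 0.00642 and 0.00842). Once the trend was subtracted, 2 higher and 3 lower were called. Sox3, Tnc, Hes6 and Tcf12 stayed called there with smaller changes (log2 0.45, -0.57, 0.40 and -0.23, against 0.99, -0.87, 1.01 and -0.60 as deposited). With the slope covariate Tnc was called at -0.55 (FDR = 0.0200), and Sox3, Hes6, Tcf12 and Btg2 (log2 0.54 as deposited) were not, at 0.34, 0.28, -0.16 and 0.35 (FDR = 0.725, 0.678, 0.687 and 0.236).

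Genes of young neurons had 5 higher and 7 lower of 34 measured (median log2 fold change -0.18, camera FDR = 0.343). The proneural factor gene Neurod1 rose from 65.8 ± 5.33 to 148 ± 24.9 (FDR = 0.00166). Map2, which encodes a microtubule-associated protein of dendrites, fell from 17464 ± 2504 to 10077 ± 1236 and Myt1l fell from 90.7 ± 12.4 to 39.7 ± 5.86 (FDR = 0.00282 and 0.00312). In values with the trend subtracted, 5 higher and 5 lower were called. Map2 and Myt1l were among them at log2 -0.47 and -0.77, against -0.79 and -1.17 as deposited, and with the covariate they were at -0.38 and -0.86 (FDR = 0.145 and 0.285). In the interneuron lineage list 0 higher and 4 lower of 14 measured were called (median log2 fold change -0.38, camera FDR = 0.633). In that list, 7 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 0 higher and 3 lower, DESeq2 0 and 4, and limma-voom 0 and 3. EdgeR and limma-voom tested only members that passed their filter, here 11 of 14. Below, 17 of 26 interferon, 12 of 13 mitochondrial and 5 of 8 hindbrain genes passed it. Of the neural crest list 5 of 8 passed, and of the genes near Phf23 15 of 20. Dlx2 fell from 22.5 ± 7.20 to 6.27 ± 3.89 (log2 -1.89, FDR = 0.0164, and -1.24 with the covariate, FDR = 0.640), and Dlx1, Six3 and Gad2 also fell. Dlx1 stayed called only without wild type 2, Phf23 knockout 1 or Phf23 knockout 4 (log2 from -1.52 to -1.17 and FDR from 0.055 to 0.0966 without each other library, against log2 -1.49 with all 8). Six3 stayed called only without wild type 3 or Phf23 knockout 2 (log2 from -0.54 to -0.43 and FDR from 0.0592 to 0.0926 without each other library, against log2 -0.50 with all 8). Gad2 stayed called only without wild type 4 or Phf23 knockout 4 (log2 from -1.20 to -0.79 and FDR from 0.0553 to 0.143 without each other library, against log2 -1.10 with all 8), and its log2 fold change was -0.78 with the trend subtracted (FDR = 0.115) and 0.19 with the covariate (FDR = 0.931).

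Astrocyte genes moved both ways, with 10 higher and 4 lower of 21 measured (median log2 fold change 0.26, camera FDR = 0.216). Gfap rose from 283 ± 30.7 to 536 ± 76.3 and S100b rose from 124 ± 5.94 to 216 ± 32.2, while the folate enzyme gene Aldh1l1 fell from 2746 ± 298 to 1479 ± 95.6 and the water channel gene Aqp4 fell from 382 ± 62.5 to 196 ± 19.8 (FDR = 0.00165, 0.00495, 0.000581 and 0.00225). On subtracted values, 6 higher and 3 lower were called, S100b among them at log2 0.47, against 0.78 as deposited. The oligodendrocyte lineage list had 8 higher and 2 lower of 21 measured (9 and 3 adjusted over the list alone, median log2 fold change 0.12, camera FDR = 0.129). Besides Mbp and Enpp6, the lineage factor gene Sox10 rose from 117 ± 10.4 to 288 ± 59.2 and Bcas1 rose from 134 ± 11.7 to 316 ± 26.9 (FDR = 0.000654 and 0.000332). With the trend subtracted 7 higher and 3 lower were called.

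**Figure D3:**
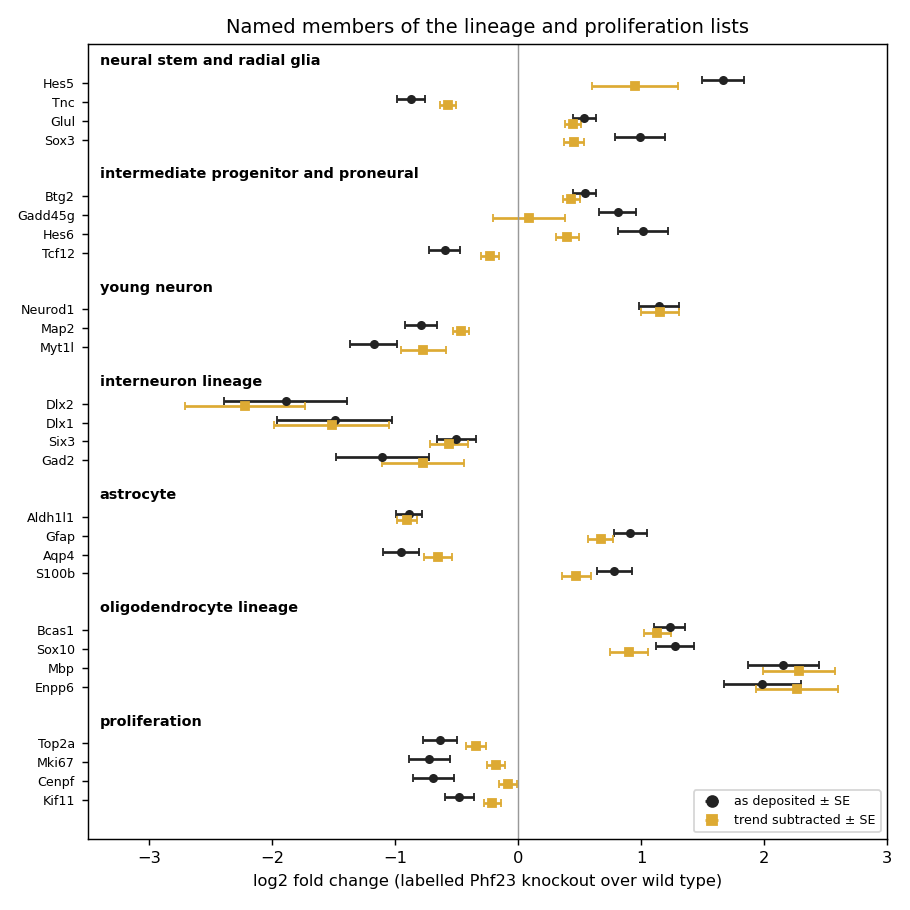
Log2 fold change (horizontal axis, libraries labelled knockout over wild type, bars are SE) of named members of the lineage and proliferation lists, as deposited (circles) and with the length and GC trend subtracted (squares). Hes5, Mbp and Enpp6 lie to the right and Dlx2 to the left, and the named proliferation genes move towards 0 with the trend subtracted.

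Of the proliferation genes, 2 higher and 6 lower of 34 measured were called (median log2 fold change -0.04, camera FDR = 0.633). Top2a fell from 13729 ± 1783 to 8892 ± 1503, Mki67 fell from 11201 ± 2432 to 6769.8 ± 1318 and Cenpf fell from 3699.5 ± 858 to 2277 ± 417 (FDR = 0.00870, 0.0107 and 0.0127). After subtraction of the trend, Top2a kept its call (log2 -0.34, against -0.63 as deposited, FDR = 0.0122), Mki67 and Cenpf lost theirs (log2 -0.18 and -0.08 against -0.72 and -0.69, FDR = 0.0979 and 0.437), and 4 members in all were lower. With the covariate Top2a, Mki67 and Cenpf were at -0.15, -0.07 and -0.03 (FDR = 0.721, 0.894 and 0.960). The p53 target list had 8 higher and 4 lower of 22 measured (median log2 fold change 0.19, camera FDR = 0.129). The cell cycle inhibitor gene Cdkn1a rose from 9662 ± 304 to 13797 ± 1171, Phlda3 rose from 2086 ± 322 to 3885 ± 597 and Sesn2 rose from 1975 ± 109 to 2876 ± 172 (FDR = 0.00560, 0.00195 and 0.00341). Once the trend was subtracted, 5 higher and 1 lower were called, and Cdkn1a and Phlda3 were not (log2 0.20 and 0.22 against 0.51 and 0.90, FDR = 0.0728 and 0.0870). Sesn2 kept its call there (log2 0.35, against 0.54 as deposited), and Phlda3 was at 0.51 (FDR = 0.108) with the covariate.

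Among signalling lists, the Notch pathway had 6 higher and 2 lower of 22 measured (median log2 fold change 0.06, camera FDR = 0.468), with Hes1 going from 1081 ± 335 to 2005 ± 399 and Rfng from 696 ± 87.3 to 1006 ± 75.5 (FDR = 0.0105 and 0.00861). Both lost their calls with the trend subtracted (log2 0.56 and 0.18 against 0.93 and 0.54, FDR = 0.0732 and 0.106), which left 1 member higher. The Wnt pathway had 6 higher and 3 lower of 27 measured (median log2 fold change -0.01, camera FDR = 0.863). Its receptor gene Lgr5 fell from 307 ± 43.0 to 129.8 ± 14.9 and the ligand genes Wnt7b and Wnt7a rose from 1358 ± 239 to 2355 ± 182 and from 1029 ± 77.1 to 1453 ± 99.5 (FDR = 0.000534, 0.00270 and 0.00649). In the hedgehog pathway 1 higher and 3 lower of 13 measured were called (1 and 4 adjusted over the list alone, median log2 fold change 0.09, camera FDR = 0.870), with the ligand gene Shh rising from 34.2 ± 4.32 to 117 ± 16.7 and the coreceptor gene Cdon falling from 1555 ± 83.5 to 952 ± 189 (FDR = 0.000385 and 0.00500). The BMP and TGF-beta list had 4 higher and 3 lower of 23 measured (median log2 fold change 0.08, camera FDR = 0.863), and its receptor gene Tgfbr1 fell from 1176 ± 79.2 to 763 ± 106 (FDR = 0.00477). The list of E proteins and Id factors, which are their inhibitors, had 5 higher and 2 lower of 14 measured (6 and 2 adjusted over the list alone, median log2 fold change 0.37, camera FDR = 0.129). Besides the fall of Tcf4, Id1 rose from 337 ± 111 to 716 ± 145 and Id4 rose from 90.5 ± 6.42 to 169 ± 12.5 (FDR = 0.00619 and 0.00249). In values with the trend subtracted, the Wnt, hedgehog, BMP and E protein lists had 5 higher and 4 lower, 2 higher and 2 lower, 4 higher and 1 lower, and 3 higher and 3 lower. Cdon, Tgfbr1 and Id1 stayed called in them with smaller changes (log2 -0.33, -0.27 and 0.57, against -0.73, -0.63 and 1.12 as deposited). With the covariate Hes1, Rfng, Cdon, Tgfbr1 and Id1 were at 0.20, 0.24, -0.28, -0.36 and 0.32 (FDR = 0.848, 0.579, 0.456, 0.305 and 0.652).

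The SIN3-HDAC list, of a histone deacetylase complex, had 7 higher and 3 lower of 24 measured (median log2 fold change 0.04, camera FDR = 0.364). Sin3b rose from 1886 ± 164 to 3048 ± 485 and Sap30 rose from 565 ± 123 to 972 ± 159, and the corepressor gene Ncor1, with a transcript of 9037 nt, fell from 5025 ± 878 to 2953 ± 756 (FDR = 0.00434, 0.00672 and 0.00895). On subtracted values, 5 higher and 1 lower were called, with Sap30 and Ncor1 at log2 0.29 and -0.31, against 0.79 and -0.78 as deposited. With the slope covariate Sin3b (log2 0.68 as deposited), Sap30 and Ncor1 were at 0.32, 0.23 and -0.07 (FDR = 0.326, 0.665 and 0.880). Genes of histone acetylation had 0 higher and 6 lower of 20 measured (0 and 7 adjusted over the list alone, median log2 fold change -0.23, camera FDR = 0.212). In that list, 10 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 0 higher and 7 lower, DESeq2 0 and 7, and limma-voom 0 and 7. Sirt1, which encodes a deacetylase, fell from 545 ± 54.2 to 401 ± 25.1 (log2 -0.44, FDR = 0.0149), and the call was lost without Phf23 knockout 1 (log2 -0.40, FDR = 0.0541). The acetyltransferase gene Ep300 fell from 1798 ± 213 to 1287 ± 307 (log2 -0.51, FDR = 0.0300), and the call was lost without wild type 1 (log2 -0.44, FDR = 0.0896), wild type 2 (log2 -0.47, FDR = 0.0852), Phf23 knockout 1 (log2 -0.36, FDR = 0.0949) or Phf23 knockout 2 (log2 -0.48, FDR = 0.0626). With the trend subtracted 1 higher and 2 lower were called, and Sirt1 and Ep300 were not (log2 -0.23 and -0.05 against -0.44 and -0.51, FDR = 0.0859 and 0.747). With the covariate these were at -0.29 and 0.04 (FDR = 0.554 and 0.957). Autophagy genes had 8 higher and 3 lower of 31 measured (median log2 fold change 0.02, camera FDR = 0.364). The lysosomal factor gene Tfeb rose from 161 ± 22.0 to 318 ± 40.2 and Gabarap, which also lies near Phf23, rose from 3250 ± 273 to 5335 ± 1470 (FDR = 0.00183 and 0.0127). After subtraction of the trend, 6 autophagy genes were higher, with Tfeb and Gabarap at log2 0.49 and 0.28, against 0.98 and 0.68 as deposited. With the covariate both lost their calls, at 0.64 and 0.04 (FDR = 0.160 and 0.950).

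Immediate early genes were the list called by camera, with 10 higher and 0 lower of 21 measured (11 and 0 adjusted over the list alone, median log2 fold change 0.42, camera FDR = 0.00403), but not with an estimated correlation (adjusted p = 0.59) or with the trend subtracted (camera FDR = 0.065). Camera also called it with each library left out, with the slope covariate and without the 4 libraries of the steepest slopes, but with an estimated correlation the adjusted p was 0.393 in the covariate fit and 0.601 without the 4 libraries. In that list, 11 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 11 higher and 0 lower, DESeq2 11 and 0, and limma-voom 10 and 0. Fos rose from 3374 ± 777 to 5489.7 ± 727, Ier3 rose from 609.5 ± 129.9 to 1114 ± 190 and the RNA-binding factor gene Zfp36 rose from 338 ± 99.2 to 639 ± 108 (FDR = 0.00869, 0.00553 and 0.00804). Once the trend was subtracted, 6 higher and 1 lower were called, and Fos and Ier3 were not (log2 0.47 and 0.33 against 0.72 and 0.88, FDR = 0.168 and 0.462). With an estimated correlation 0 of the 30 lists were called as deposited, where the lowest unadjusted p was 0.0664, and 0 in each of the 3 fits that concern transcript length. Fry called 7 lists, which were neural stem, oligodendrocyte, mural, p53, E protein, SIN3-HDAC and autophagy.

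The integrated stress response list had 6 higher and 1 lower of 21 measured (median log2 fold change 0.22, camera FDR = 0.129), and the list of hypoxia and glycolysis 8 higher and 2 lower of 23 measured (8 and 3 adjusted over the list alone, median log2 fold change 0.09, camera FDR = 0.212). The cystine transporter gene Slc7a11 fell from 241 ± 29.5 to 136 ± 26.1 (FDR = 0.00642) and lost its call with the trend subtracted (log2 -0.27 against -0.83, FDR = 0.174). The glycolytic enzyme genes Aldoa and Tpi1 rose from 9636 ± 1312 to 17540 ± 3858 and from 5211 ± 619.7 to 8869 ± 1798 (FDR = 0.00498 and 0.00587). Cholesterol synthesis genes had 7 higher and 1 lower of 21 measured (median log2 fold change 0.04, camera FDR = 0.216), with Mvk going from 684 ± 109.8 to 1161 ± 187 and Msmo1 from 2757 ± 233 to 3741 ± 341 (FDR = 0.00553 and 0.0107). In values with the trend subtracted, the 3 lists had 3 higher and 1 lower, 6 higher and 1 lower, and 6 higher and 1 lower, and cholesterol synthesis was called as higher (camera FDR = 0.0215), but not with an estimated correlation (adjusted p = 0.75). Aldoa, Tpi1 and Mvk stayed called in these values with smaller changes (log2 0.36, 0.36 and 0.46, against 0.85, 0.75 and 0.76 as deposited). With the covariate Slc7a11, Aldoa, Tpi1 and Mvk were at -0.35, 0.25, 0.19 and 0.26 (FDR = 0.603, 0.429, 0.552 and 0.532). The interferon list had 0 higher and 2 lower of 26 measured (0 and 1 adjusted over the list alone, median log2 fold change -0.04, camera FDR = 0.854), and Ifit2 fell from 255 ± 13.8 to 128 ± 15.1 (FDR = 0.000970). In that list, 5 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 0 higher and 1 lower, DESeq2 0 and 2, and limma-voom 0 and 1. Of mitochondrially encoded genes, 0 higher and 0 lower of 13 measured were called (median log2 fold change 0.13, camera FDR = 0.633). In that list, 3 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 0 higher and 0 lower, DESeq2 1 and 0, and limma-voom 1 and 0, and 5 were higher without the 4 libraries of the steepest slopes.

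**Figure D4:**
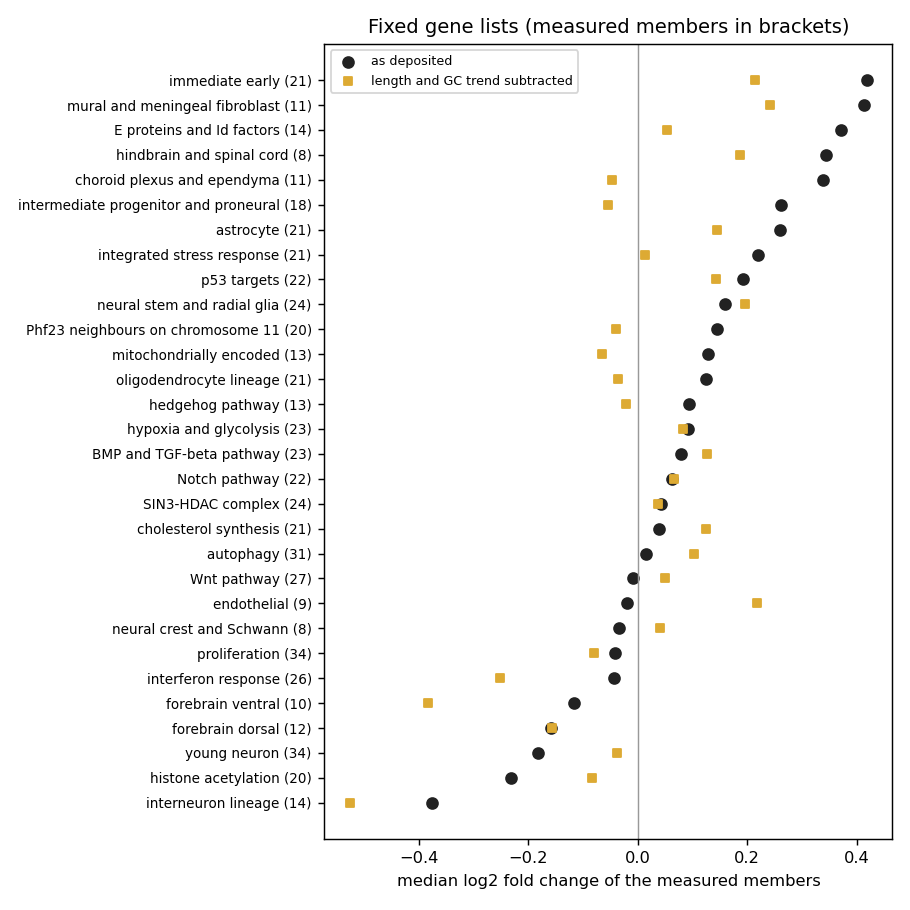
Median log2 fold change (horizontal axis, libraries labelled knockout over wild type) of the measured members of each of 30 gene lists, as deposited (circles) and with the length and GC trend subtracted (squares), with the number of measured members in brackets. Immediate early genes have the highest median as deposited, at 0.418, and interneuron lineage genes the lowest, at -0.376.

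None of the 3 lists of regional identity was called by camera. The dorsal forebrain list had 1 higher and 1 lower of 12 measured (median log2 fold change -0.16, camera FDR = 0.872). Lmo3 fell from 593 ± 48.0 to 448 ± 17.6 (log2 -0.40, FDR = 0.0153), and the call was lost without wild type 1 (log2 -0.35, FDR = 0.0544) or wild type 2 (log2 -0.39, FDR = 0.0516). Dmrta2 rose from 540.3 ± 204 to 859 ± 39.1 (log2 0.75, FDR = 0.0219), and the call was lost without wild type 1 (log2 0.59, FDR = 0.07), wild type 2 (log2 0.58, FDR = 0.0728) or Phf23 knockout 1 (log2 0.74, FDR = 0.0634). The ventral list had 2 higher and 4 lower of 10 measured (3 and 4 adjusted over the list alone, median log2 fold change -0.12, camera FDR = 0.863), with Zic1 rising from 411 ± 42.2 to 834 ± 96.1 and Ebf1 from 50.1 ± 8.87 to 96.1 ± 17.4 (FDR = 0.000581 and 0.00869) while Dlx1 and Dlx2 fell. The hindbrain and spinal cord list had 2 higher and 0 lower of 8 measured (2 and 1 adjusted over the list alone, median log2 fold change 0.34, camera FDR = 0.481). In that list, 5 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 1 higher and 1 lower, DESeq2 3 and 1, and limma-voom 1 and 0. On subtracted values, the dorsal, ventral and hindbrain lists had 1 higher and 2 lower, 2 higher and 5 lower, and 2 higher and 1 lower. Lmo3 and Dmrta2 were called there at log2 -0.26 and 0.37, against -0.40 and 0.75 as deposited, and Dmrta2 was at 0.23 (FDR = 0.874) with the covariate.

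None of the 4 tested lists of other cell types was called by camera. The endothelial list had 1 higher and 1 lower of 9 measured (0 and 1 adjusted over the list alone, median log2 fold change -0.02, camera FDR = 0.916), and Flt1 fell from 30.6 ± 2.40 to 8.31 ± 5.27 (FDR = 0.00769). The mural and meningeal list had 2 higher and 1 lower of 11 measured (median log2 fold change 0.41, camera FDR = 0.364). Foxc1 rose from 212 ± 39.4 to 426 ± 23.2 and Cspg4 fell from 2336 ± 78.4 to 1414 ± 281 (FDR = 0.00130 and 0.00405). The choroid plexus and ependyma list had 1 higher and 1 lower of 11 measured (0 and 0 adjusted over the list alone, median log2 fold change 0.34, camera FDR = 0.870). Otx2 stayed called only without wild type 2 or Phf23 knockout 4 (log2 from -1.75 to -1.41 and FDR from 0.0551 to 0.121 without each other library, against log2 -1.63 with all 8). Ccdc153 stayed called only without wild type 4 or Phf23 knockout 4 (log2 from 0.94 to 1.64 and FDR from 0.0564 to 0.13 without each other library, against log2 1.42 with all 8). The neural crest and Schwann list had 2 higher and 0 lower of 8 measured (median log2 fold change -0.04, camera FDR = 0.863), where 2 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 2 higher and 0 lower, DESeq2 2 and 0, and limma-voom 2 and 0. Those 2 were Egr2 and Cdh19 (log2 0.52 and 0.45), and Egr2 was not called without wild type 2 (log2 0.39, FDR = 0.0576) or Phf23 knockout 1 (log2 0.45, FDR = 0.0674). Cdh19 was not called without wild type 3 (log2 0.37, FDR = 0.0947), wild type 4 (log2 0.41, FDR = 0.0719), Phf23 knockout 1 (log2 0.47, FDR = 0.0722), Phf23 knockout 3 (log2 0.47, FDR = 0.0615) or Phf23 knockout 4 (log2 0.36, FDR = 0.0663). With the trend subtracted these 4 lists had 1 higher and 1 lower, 1 higher and 1 lower, 0 higher and 1 lower, and 2 higher and 1 lower. Ccdc153 was not called there (log2 0.95 against 1.42, FDR = 0.156). With the covariate Cspg4 (log2 -0.74 as deposited), Otx2 and Ccdc153 were at -0.39, -0.89 and 0.43 (FDR = 0.294, 0.809 and 0.895). Lists with fewer than 5 measured members were not tested. For microglia limma-trend called 0 of 4, with 0 at an unadjusted p under 0.05, and DESeq2 called 0 of 4, while edgeR and limma-voom called 0 of the 2 that passed their filter. For erythroid genes it called 0 of 3, with 0 at an unadjusted p under 0.05, and DESeq2 called 0 of 3, while edgeR and limma-voom tested 0 of them. Of 4 Y-linked genes Kdm5d, Uty and Ddx3y fell, and none was called with the trend subtracted (log2 -0.15, -0.18 and -0.10 against -0.63, -0.54 and -0.41, FDR = 0.210, 0.176 and 0.537), when 0 had an unadjusted limma-trend p under 0.05.

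Genes near Phf23 on chromosome 11 had 5 higher and 0 lower of 20 measured (median log2 fold change 0.14, camera FDR = 0.191). In that list, 8 had an unadjusted limma-trend p under 0.05 in either direction, edgeR called 6 higher and 0 lower, DESeq2 6 and 0, and limma-voom 6 and 0. Tmem256 rose from 689 ± 52.4 to 1324 ± 353 (FDR = 0.00495), and Eif5a went from 11443 ± 1248 to 15706 ± 3247. Eif5a stayed called only without wild type 4 or Phf23 knockout 4 (log2 from 0.32 to 0.48 and FDR from 0.0536 to 0.11 without each other library, against log2 0.44 with all 8), and with the trend subtracted it was at -0.03 (FDR = 0.790). After subtraction of the trend, 3 higher and 1 lower were called. Tmem256 was called at log2 0.33, against 0.90 as deposited, and with the covariate Tmem256 and Eif5a were at 0.31 and -0.10 (FDR = 0.493 and 0.799). The median and the camera direction of a list differed in sign for the endothelial and Wnt lists (median below 0, mean above 0, camera up). They also differed for the hedgehog list (median and mean above 0, camera down) and for the neural crest and ventral forebrain lists (median and mean below 0, camera up).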

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

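In this part, the tests of the length and GC trend, of Tcf4 and Phf23 with exchanged labels or altered RNA, and of Xist were chosen only after the result was seen, as were the alternatives that subtract the trend, use the slope as a covariate or leave out the 4 steepest libraries.

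Of 332 groups of 4 libraries, 16 had a library whose gap to the nearest other exceeded the 95% critical share of the group's range by Dixon's test, and chance gives about 1 in 20. On the log2(value + 1) scale, libraries labelled wild type stood apart for Serpinb11 in wild type 2 (0.97), Egr2 in wild type 2 (9.57), Lgr5 in wild type 1 (8.54), Id4 in wild type 3 (6.66), Slc7a11 in wild type 3 (7.63) and Pax7 in wild type 4 (2.77). Libraries labelled knockout stood apart for Hp in Phf23 knockout 3 (1.52), Glul in Phf23 knockout 3 (12.66), Bcas1 in Phf23 knockout 2 (8.48), Kif11 in Phf23 knockout 1 (11.58), Tgfbr1 in Phf23 knockout 4 (9.85), Psmb9 in Phf23 knockout 1 (5.67) and Egln3 in Phf23 knockout 3 (9.99). The mean of the endothelial list stood apart in Phf23 knockout 3 (3.91) and that of the interferon list in Phf23 knockout 1 (5.21). Wild type 3 had 15647304 recovered reads, against 17982640 in the nearest library of its group. Kif11 lost its limma-trend call without Phf23 knockout 1, with a change about as large (log2 -0.41 against -0.48, FDR = 0.0529).

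The first pattern is the number of calls together with long transcripts lower in the libraries labelled knockout, Tcf4 among them. The real split of the 8 libraries was the 1 of 35 splits with as many calls (4593 genes, 0 in the highest other). With the trend subtracted it was again 1 of 35 (2826 genes, 0 in the highest other). This argues against chance for both counts but cannot exclude it, because 1 of 35 is the smallest share possible. For lists, 24 of 35 splits called as many (1 list, 8 in the highest other), so chance is not argued against there. A smooth trend with the length and GC content of the longest annotated transcript as the whole cause is argued against. Of 15538 genes, 1854 (11.93%) were called before and after it was subtracted in the same direction, while Tcf4 shrank from -0.82 to -0.29. A trend with the length of the transcripts actually expressed was not tested and stays open. A wider difference in library quality that the length slope tracks may contribute: after subtraction, the genotype difference correlated across genes at 0.558 with that predicted from the slopes within genotypes, above 98 of 100 shuffles (highest of these 0.513), the other 2 being the real order drawn again. For Tcf4 the covariate value of -0.31 ± 0.108 (before, -0.82 ± 0.140) kept its sign but lost its call as the difference shrank. A lost call decides little there. On simulated data that fit recovered 2% of 1.5-fold and 28% of 2-fold changes, shares that may be understated. Without the 4 steepest libraries Tcf4 was called at -0.48 (FDR = 0.000405), in a fit of wild type 3 and 4 against Phf23 knockout 3 and 4 only. Because the slopes differ between genotypes in both sets of libraries, the genotype and the slope cannot be told apart for Tcf4. An effect of the knockout stays open.

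The second pattern is Phf23 higher in the libraries labelled knockout. The length slope as the whole cause is argued against by the covariate value of 0.65 ± 0.127, which stayed called (FDR = 0.0172). Single libraries exchanged between the genotypes are argued against by a gap of 0.565 on the log2 scale between the lowest library labelled knockout and the highest labelled wild type. RNA still made from the altered allele may account for the presence of Phf23 reads, and this stays open because the table has 0 values per exon. By itself it does not say why the value lies above wild type, and that was not tested. An exchange of all 4 labels of a genotype with the other 4 stays open too, since a ratio of 1.86 decides nothing where the nature of the altered allele is not given in the sources used here.

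The third pattern is that no library held female cells. The highest Xist value was 7.75 normalised reads (8 reads), which is 0.68% of the lowest value of the Y-linked gene Eif2s3y, 1140, so a mixed or female library is argued against. Libraries of 8 independent animals would share 1 sex with a chance of 0.781%, so the libraries may come from few animals or from selected embryos, and no biological explanation was tested.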

How the results depend on the processing

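In this part, edgeR on the recovered reads, limma-trend with TMM or library size only, the subtracted trend, the slope covariate, the fit without the 4 steepest libraries, the estimated correlation in these last 3 and the minimum mean of 10 were chosen after the data were seen. Phf23 stayed called in each setting run (log2 0.54 to 0.96, highest FDR 0.0271; 0.85 to 0.96 with a library left out). Tcf4 kept its direction (-0.93 to -0.29; -0.93 to -0.73 with a library left out) but not its call with the replicate block (-0.82, FDR = 0.0518) or the slope covariate (-0.31, FDR = 0.27). For named genes, Phf23 and Tcf4 included, 2647 values kept direction and side of the threshold, 368 lost the call, 27 gained it and 9 reversed, and for lists 504, 6, 19 and 41. Where no reason is given, the cause was not tested.

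Called genes numbered 333 (151 higher, 182 lower) with the replicate block and 1884 to 5861 (948 to 2919 higher, 936 to 2942 lower) with a library left out. They numbered 2826 (1498, 1328) with the trend subtracted, 170 (102, 68; 1617 at an unadjusted p under 0.05) with the slope covariate, 1422 (717, 705) without the 4 steepest libraries, where fewer samples were tested, and 556 (247, 309) at a log2 change of at least 1, a stricter limit. By edgeR, DESeq2 (1507 genes with no adjusted p) and limma-voom 4683, 5215 and 4694 were called. A minimum mean of 1 removed no gene, and in simulation the covariate recovered 28% of 2-fold changes, which may be understated.

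Lists called numbered 0 with an estimated correlation, 7 by fry, 2 with the trend subtracted, 6 with the covariate and 6 without the 4 steepest libraries. Those 6 were neural stem, p53, Notch, hypoxia, cholesterol and immediate early both times, and 0 were called in any of these 3 fits with an estimated correlation. The neural stem list passed the threshold by fry (FDR = 0.0164), subtracted (0.0337), with the covariate (0.000472) and without the 4 libraries (0.000739), but with an estimated correlation its adjusted p was 0.59 as deposited and 0.678, 0.393 and 0.601 in the 3 fits. Directions reversed, none with a call, as follows (FDR, then that with an estimated correlation after a slash). By fry: endothelial 0.989, hedgehog 0.624. Subtracted: intermediate progenitor 0.971 / 0.975, choroid 0.743 / 0.83, hedgehog 0.943 / 0.95, mitochondrial 0.86 / 0.95, ventral 0.699 / 0.83. Covariate: young neuron 0.88 / 0.918, choroid 0.623 / 0.698, hedgehog 0.395 / 0.698, histone acetylation 0.623 / 0.698, integrated stress 0.76 / 0.881, ventral 0.76 / 0.898. Without the 4 libraries: choroid 0.798 / 0.929, hedgehog 0.985 / 0.985, BMP 0.985 / 0.985, ventral 0.798 / 0.929. With a library left out, FDR ranges were endothelial 0.756 to 0.976, Wnt 0.515 to 0.97, ventral 0.681 to 0.936, dorsal 0.756 to 0.973, hedgehog 0.781 to 0.995 and mitochondrial 0.263 to 0.924.

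Genes reversed with the covariate were Gad2 (log2 0.19), Ptch1 (0.082), Kat6a (0.16), Ep300 (0.040), mt-Nd4l (0.56) and Eif5a (-0.10). Once the trend was subtracted, they were Foxj1 (-0.046) and Eif5a (-0.029), and without the 4 libraries mt-Nd4l (0.34). None was called there.

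No sign was found that equal replicate numbers pair the libraries, but the check cannot exclude it. Correlations of same-numbered deviations were -0.149, -0.0524, -0.0826 and -0.128, and the best match was never the own number (0.176, 0.0866, 0.112 and 0.148). These values still held the length trend. Slopes were highest in wild type 1 and 2 and lowest in Phf23 knockout 1 and 2, which lowers same-numbered correlations whether or not libraries are paired. All 333 calls of the replicate block were among the 4593.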

Other observations

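In this part, the gene families and genes were chosen after their values were seen, and the subtracted trend, the slope covariate and the fit without the 4 libraries of the steepest slopes were added after the data were seen.

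Most nuclear genes of the respiratory chain, whose transcripts are short, were called higher as deposited in the libraries labelled knockout. Of 75, limma-trend called 70 higher (median log2 0.81, median transcript 983 nt), 40 with the trend subtracted (median 0.35) and 0 with the slope covariate, with 8 at an unadjusted p under 0.05. Without the 4 libraries of the steepest slopes 44 were higher. Of 82 cytosolic ribosomal protein genes, 54 were higher, against 12 higher and 5 lower with the trend subtracted, 0 higher and 1 lower with the covariate, and 3 higher and 1 lower without the 4 libraries of the steepest slopes. Of 49 clustered protocadherin genes 10 were lower and 1 higher, with the trend subtracted 10 and 3, and with the covariate 0 and 0 by limma-trend, where 6 had an unadjusted p under 0.05. Zic4 rose from 19.5 ± 3.0 to 39.2 ± 11.4 normalised reads (FDR = 0.0204), and it overlaps Zic1 on chromosome 9, so that their reads cannot be fully told apart. GABA-A receptor subunit genes fell for 5 of 11 and rose for 1, with the trend subtracted 5 fell and 2 rose, and with the covariate 3 fell. On chromosome 5, Gabra2 fell from 2188 ± 236 to 1015 ± 183, Gabra4 from 199 ± 31.1 to 68.3 ± 17.4 and Gabrb1 from 415 ± 90.0 to 125 ± 16.2 (FDR = 0.000596, 0.000835 and 0.000297), and each stayed called with the covariate (FDR = 0.0173, 0.0338 and 0.00615). The changes of Gabra2 and Gabrb1 were smaller with the trend subtracted (log2 -0.73 and -1.04, against -1.12 and -1.71 as deposited), and with the covariate they were at -0.67 and -1.34. Gabra4 and Gabrb1 overlap. Gabrg1 beside them had 946 ± 104 and 866 ± 39.2 (FDR = 0.409). Of 336 genes named Zfp, 70 were lower and 20 higher, and with the trend subtracted 24 and 14, and with the covariate 0 and 0 by limma-trend, where 20 had an unadjusted p under 0.05. Of 20 ephrin and Eph receptor genes, 3 were higher and 2 lower, with the trend subtracted 4 and 4, and with the covariate 1 and 2.

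By limma-trend as deposited, with the trend subtracted and with the slope covariate, 123 genes were called in all 3 fits, 65 higher and 58 lower. The iron reductase gene Cybrd1 fell from 2546 ± 358 to 752 ± 67.9 (log2 -1.75, FDR = 1.6e-05). The surface glycoprotein gene Thy1 fell from 1355 ± 185 to 556 ± 121 and the cell adhesion gene Chl1 fell from 5084 ± 835 to 1966 ± 301 (FDR = 0.000581 and 0.000297). Chl1 was called with a smaller change with the trend subtracted (log2 -0.88, against -1.37 as deposited) and with the covariate, at -0.87 (FDR = 0.000845). Dhh, which encodes a hedgehog ligand, fell from 311 ± 28.8 to 133 ± 16.1 (FDR = 0.000468) where Shh rose.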
